A study of Homo sapiens with 2 samples.

How the data were processed

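The series holds 2 one-colour arrays of human cells labelled PC3, 1 for a control and 1 for cells carrying Cas9 and a guide RNA against HIC1. Per the labels' protocols, Cas9 and the guide came from separate lentiviral plasmids, the loss of HIC1 was assessed by western blot, and total RNA was labelled with Cy3. The blot was not analysed here. Groups were taken from the labels, and nothing in them gives a replicate of either group. Both arrays lay on slide 1 and in scan 1, so slide and scan do not differ between the groups. Batches of culture, RNA and labelling are not given in the sources used here. The knockout sample's title ends in the number 4, and the labels do not say whether this is a clone, a guide or a replicate.

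Per the file headers, spot intensity was read and background-subtracted with Agilent Feature Extraction 10.7.1.1, with spatial and multiplicative detrending, and not normalized between arrays. The deposited processed intensity values carry 3 significant digits. The headers name hg19 as the design's build. Each array had 60901 gene spots for 58201 probes, of which 29724 (48.8%) were well above background on the control array and 29909 (49.1%) on the knockout array. No gene spot was saturated. Of 308 negative control spots per array the median processed signal was 4.81 and 3.86. Replicate spots of a probe had a median SD of 0.025 and 0.031 log2 units, over 272 and 276 probes.

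The deposited value table holds log2-like values for the same arrays, with the same quantiles in both columns and a median of 4.18 in each. Its scale is inferred from the values, and its centring is unknown. Its rows did not match the scanner values of the probes they name. Across probes Spearman's rho was 0.02 for both columns, and across 10 spike-in probes it was 0.31 for the control and 0.19 for the knockout array. No row of it was therefore named, its direction was not settled, and no comparison with it as the source of the values was run.

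Control spots and spots with outlier marks were left out, the latter being 1217 gene spots (2.00%) on the control array and 871 (1.43%) on the knockout array, which removed 1524 probes. Replicate spots were averaged on the log2 scale. A probe counted as detected where over 50% of its remaining spots were well above background. Because under 50% of the probes were detected, log2 processed signals were scaled by each array's 75th percentile over the probes detected on both arrays, which stood at signals of 1836 and 1320. A gene took the value of its brightest probe among those detected on both arrays. Names came through RefSeq accessions of GRCh38.p14 for 30299 of 56677 probes (53.5%) and otherwise from the array's design, which can be old. No coordinates were taken from that assembly. Of 42480 genes with a probe, 19460 were measured on both arrays. For a gene detected on 1 array alone the fold is a lower bound, against the higher of the other array's lowest signal well above background and the dim probe's own. The number of arrays limits the precision.

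With 1 array per group no test was possible, so genes were sorted by a 2-fold threshold. Each of 30 gene lists, fixed before the data were examined, was described by its median log2 difference and that median's percentile among 10000 random lists of the same size matched on level in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. The lists were reported HIC1 targets, p53 response, epithelial junction and keratin, mesenchymal, extracellular protease and invasion, mitotic proliferation, DNA replication, inflammatory cytokine and NF-kB, type I interferon response, antigen presentation, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis and oxidation, oxidative phosphorylation and ribosomal protein. The rest were ribosome biogenesis and MYC targets, endoplasmic reticulum stress and ATF4, heat shock, NRF2 antioxidant, immediate early, metallothionein, neuroendocrine, stem and basal cell, Wnt targets, TGF-beta targets, ephrin and axon guidance, leukocyte markers, endothelial and fibroblast markers, replication-dependent histones and 1 list left unnamed, since some items are not reported here.

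The genes named were HIC1, the 15 largest differences each way among genes whose probes all went the same way, and the 5 largest bounds for each array. Names that begin as locus, LINC, lncRNA or accession identifiers were left out of these differences and bounds. From each list came up to 4 members at least 2-fold apart, or the 2 largest where none was, and SIRT1, ACKR3, CCND1, EPHA2 and SOX9 were named whatever their values. Other list members, the line markers and second probes were named after their values were seen.

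The alternatives were normexp background correction with an offset of 50 in limma 3.58.1 (R 4.3.3), quantile normalization, loess with a span of 0.3, the 75th percentile over all probes, no filter on dim probes, a filter at the median level, outlier-marked spots kept, the median over a gene's probes, and another detection mark. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data for the knockout against control comparison over 20719 genes. Planted log2 changes of 1.5 and -3.0 were recovered in 98.0% of genes, and those of -1.5 and 3.0 in all. No unchanged gene passed 2-fold, and 7.00% of 200 null lists fell beyond the limits. The simulated knockout was the control array with planted changes and added noise of SD 0.2 log2 units. The real differences had an SD of 0.50 over all measured genes. The simulation therefore checks the steps and gives no rate of false 2-fold genes for these arrays.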

Results

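Gene expression was measured in cells labelled PC3, an established human prostate cancer line, after CRISPR-Cas9 targeting of HIC1 and in control cells. HIC1 (hypermethylated in cancer 1) encodes a zinc finger transcriptional repressor. Total RNA of each culture was labelled with Cy3 and hybridised to a one-colour Agilent array, with 1 array for the control and 1 for the knockout. Of 56677 probes used, 26479 (46.7%) were well above background on the control array and 26631 (47.0%) on the knockout array, and 19460 genes were measured on both. The comparison addresses which genes differ in level between HIC1 knockout cells and their control. There were no replicates, so no difference has a replicate check and no p-values are given. Values are log2 differences, knockout minus control, and errors come from the scanner's error model, which for the named genes measured on both arrays lay between 0.20 and 0.34. The median difference of all measured genes was 0.07, or -0.01 with the percentile taken over all probes. Counts of genes above or below 0 therefore depend on the scaling, and 0 is not the midpoint of all genes.

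HIC1 itself was not well above background on either array. Its only probe gave a processed signal of 12.2 with a scanner error of 5.08 on the control array and 6.34 with an error of 4.05 on the knockout array. The lowest signals well above background were 23.4 and 18.8, and 10 and 17 of 308 negative control spots were brighter than the HIC1 probe. No fold is therefore given, and the transcript level cannot check the labels. The probe lies at chromosome 17, 1962633 to 1962692 on the plus strand (hg19), and the array annotation places it from base 2808 of the transcript. The labels give the guide as CCGCCGCGAAATGGGTCGGAAGG. Its last 3 bases, AGG, and those of its reverse complement, CGG, both read as a Cas9 PAM, so its strand stays open, and its genomic position was not determined here. An edit outside the probe need not change the probe's signal.

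Among genes reported as HIC1 targets, the knockout array had more CDKN1C, which encodes the cell cycle inhibitor p57, and less SNAI2, which encodes the transcription factor Slug. CDKN1C was 2.21-fold higher (log2 1.14) and SNAI2 2.45-fold lower (-1.29), or -0.63 with normexp background correction. The remaining 8 of 10 measured targets were within 2-fold, including the chemokine receptor gene ACKR3 (0.46), the deacetylase gene SIRT1 (-0.19) and the cyclin D1 gene CCND1 (-0.08). SOX9 was well above background on the control array alone, and EPHA2 on neither. The list's median of 0.03 lay at percentile 51.8 of 10000 random lists matched on level. With the median over all probes of a gene in place of the brightest probe, the list's distance from the random median was 0.32, at percentile 98.9.

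Across all measured genes, the largest named differences included a kallikrein protease, cancer-testis antigens and the cytokine gene TNF on the higher side, and an RNA-binding protein gene, TAF15, on the lower side. KLK8, which encodes a secreted serine protease of the kallikrein family, was 13.6-fold higher in the knockout array (log2 3.77, scanner error 0.26). The cancer-testis genes PAGE2B (3.33) and PAGE2 (2.65) were also higher, though their near-identical sequences mean that the probes may not tell them apart. PIGR, the receptor that carries IgA across epithelia, was higher by 2.98, the TNF family ligand gene CD70 by 2.84 and TNF by 2.81. HINT3, a histidine triad nucleotide-binding protein gene, was higher by 2.64 and had the brightest control signal of these genes, at 2470. The others were ESAM-AS1 (2.71), STON1 (2.67, and 0.90 on its other probe), CRABP1 (2.55), DEFB131B (2.45), SLC25A26 (2.45), LDLRAD1 (2.45), COL13A1 (2.39) and ATP8B3 (2.32). Control signals of DEFB131B (25.4), PIGR (27.1), CD70 (31.3), PAGE2 (31.4) and PAGE2B (35.4) lay near the lowest signal well above background, 23.4. Of these higher genes only STON1 and LDLRAD1 had a second probe detected on both arrays. The others rest on 1 probe each, and the scanner error does not cover differences between probes.

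On the lower side, TAF15, of the FET family of RNA-binding proteins, was 7.94-fold lower (log2 -2.99, scanner error 0.20), from a control signal of 12700. RN7SL1, the RNA of the signal recognition particle, was 4.80-fold lower (-2.26) from a control signal of 147000. NNMT, which methylates nicotinamide, was lower (-2.11), as was MYOD1, the myogenic transcription factor gene (-2.17). The others were GRXCR2 (-2.90), ESPNL (-2.58), HTR5A-AS1 (-2.58), PTPN21 (-2.49), PRR22 (-2.39), FOXD4 (-2.20), TSPAN10 (-2.07, but -0.23 on its other probe), UFSP1 (-2.02), MTG1 (-2.02), ACTL10 (-2.00) and LRRK1 (-1.93). Knockout signals of GRXCR2 (24.8), PRR22 (32), ESPNL (33.1) and LRRK1 (33.1) lay near that array's lowest signal well above background, 18.8. The smallest differences among the alternatives were -1.32 for ESPNL, -1.17 for PRR22 and -1.19 for MTG1. Of these lower genes only TSPAN10 and UFSP1 had a second probe detected on both arrays. Genes well above background on the knockout array alone were led by AHSP and VN1R3 (each at least 7.73-fold), SPINK13 (at least 7.07-fold), and SPMAP2L and SAA2 (each at least 6.78-fold). Those on the control array alone were led by MPEG1 (at least 7.46-fold), NFKBIZ (6.81), MMP27 (6.39), G6PC2 (5.05) and C17orf107 (4.44).

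In all, 746 genes (3.83%) were at least 2-fold higher and 328 (1.69%) at least 2-fold lower in the knockout array, and 56 and 18 passed 4-fold. The higher genes thus made up 69.5% of the 2-fold genes, against 54.9% after quantile normalization, 57.2% after loess and 59.1% with the percentile taken over all probes. A further 1225 genes were well above background on the knockout array alone, 338 of them by at least 2-fold, and 1082 on the control array alone, 189 of them by at least 2-fold. Many of the 2-fold genes were dim: the median control signal was 80.1 for the higher and 276.5 for the lower genes, against 516 for all measured genes. With normexp background correction, which shrinks differences of dim genes, 312 genes were at least 2-fold higher and 106 lower, and KLK8 came to 2.62, PAGE2B to 2.01 and GRXCR2 to -1.43. Named genes that then fell short of 2-fold were LRRK1 (-0.89), SNAI2 (-0.63), ZMAT3 (0.93), BIRC3 (0.97), CA9 (0.90), MSMO1 (0.86), AKR1C1 (0.89), ACP3 (-0.32), ITGB4 (0.89), JAG1 (-0.66), CD8A (0.71) and CD3E (0.73). MSMO1 and AKR1C1 also did so after quantile normalization (0.95 and 0.97), after loess (0.96 and 0.98) and with the percentile over all probes (0.93 and 0.94). Among 4380 genes with at least 2 probes, the differences of the 2 brightest probes had an SD of 0.54 between them and correlated at r = 0.39 across genes, which are not independent replicates. Of 159 2-fold genes with a second probe, 130 (81.8%) went the same way on it and 52 were again at least 2-fold apart.

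**Figure D1:**
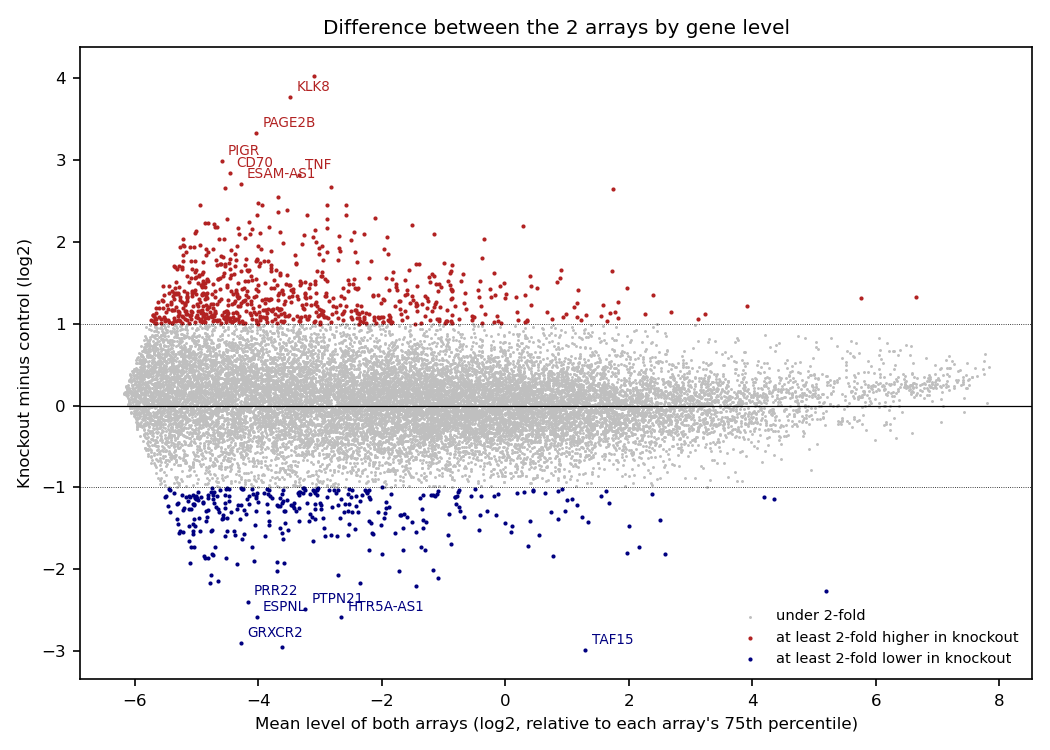
Each point is 1 of the 19460 genes measured on both arrays, with the mean level of both arrays on the x axis and the knockout minus control difference on the y axis, both in log2 units. The 746 genes at least 2-fold higher are red and the 328 at least 2-fold lower are blue; the red points lie mostly at low levels, and the 6 largest differences each way among the genes named by rule carry their symbols.

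The list medians of NF-kB, interferon response and antigen presentation genes lay above the random limits, although most members were within 2-fold. Of 13 measured inflammatory cytokine and NF-kB genes, 4 were at least 2-fold higher and none at least 2-fold lower. These 4 were TNF (2.81), the chemokine genes CCL2 (1.88) and CCL20 (1.77) and the apoptosis inhibitor gene BIRC3 (1.52). They were dim, with control signals of 68.2, 150, 60.5 and 58.7 in that order, against a median of 516 for all measured genes. The NF-kB subunit gene NFKB2 was at 0.84, whereas NFKB1 (-0.65) and IL11 (-0.83) lay below 0. ICAM1 was well above background on the knockout array alone, and 12 others, including IL6, CXCL8 and IL1B, on neither. The list's median was 0.53, at percentile 99.6 of the matched random lists.

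Of 20 measured type I interferon response genes, BST2, which encodes the antiviral protein tetherin, was at least 2-fold higher (1.94 and 1.38 on its probes) and 19 were within 2-fold. IFI44L (0.83) and OASL (0.74) lay above 0 and IFIT2 (-0.71) below it. The interferon median was 0.41, at percentile 99.6. All 16 measured antigen presentation genes were within 2-fold, but 14 lay above 0, among them the MHC class I genes HLA-E (0.58), HLA-B (0.57) and HLA-C (0.51) and the class II gene HLA-DPB1 (0.83). Their median was 0.40, at percentile 99.9. Of 10 measured leukocyte markers, 3 were at least 2-fold higher, among them CD8A (1.40) and CD3E (1.22) from control signals of 30.7 and 36.4, near the detection floor, and that list's median of 0.09 did not stand apart (percentile 41.3). The NF-kB list came to percentile 96.9 with no filter on dim probes, where its distance from the random median fell from 0.44 to 0.016. With the stricter filter only 3 of its genes remained (percentile 98.0), and the interferon list came to percentile 88.3.

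The medians of the metallothionein, p53 response and ribosomal protein lists also lay above the limits. All 8 measured metallothionein list genes lay above 0, with a median of 0.47 at percentile 99.9. The zinc exporter gene SLC30A1 was 2.49-fold higher (1.31), and MT1E (0.59), MT1X (0.45) and MT2A (0.39), which encode small zinc- and copper-binding proteins of near-identical sequence, were within 2-fold. In the p53 response list, 3 of 20 genes were at least 2-fold higher: the BH3-only gene BBC3 (1.64), the cell cycle inhibitor gene CDKN1A (1.57) and the RNA-binding protein gene ZMAT3 (1.24). The other 17 were within 2-fold, and the p53 targets BAX (-0.79), TP53I3 (-0.52) and MDM2 (-0.15) lay below 0, which left a median of 0.21 at percentile 97.8, or 81.5 with the stricter filter on dim probes. All 27 measured ribosomal protein genes lay above 0 but within 2-fold, with a median of 0.24 at percentile 98.4, led by RPS2 (0.47) and RPLP1 (0.39). After quantile normalization only 8 of these 27 lay above 0 and 16 below, RPS2 was at 0.00, and the list's distance from the random median turned to -0.03. The list also lost its place after loess (percentile 78.6) and with the stricter filter on dim probes (percentile 85.0).

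The list medians of ribosome biogenesis, DNA replication, heat shock and replication-dependent histone genes lay below the random limits, although nearly all members were within 2-fold. Of 23 measured ribosome biogenesis and MYC target genes, 20 lay below 0 and ODC1, the rate-limiting enzyme of polyamine synthesis, was at least 2-fold lower (-1.15). The snoRNP gene NOP56 (-0.88), the RNA polymerase I gene POLR1A (-0.86), the nucleolin gene NCL (-0.60) and MYC itself (-0.45) were within 2-fold. The list's median of -0.41 was below all 10000 random medians, although a second POLR1A probe gave 1.45. All 23 measured DNA replication genes were within 2-fold, 18 of them below 0, with a median of -0.27 at percentile 0.10. They included the helicase genes MCM3 (-0.54) and MCM5 (-0.54), the cyclin gene CCNE2 (-0.69) and PCNA (-0.32).

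By contrast, the 24 mitotic genes were split evenly, 12 above and 12 below 0, with CDK1 at 0.66, CCNA2 at -0.51 and a median of 0.00 (percentile 49.1). All 18 measured heat shock genes were within 2-fold and 15 lay below 0. The chaperone genes HSPH1 (-0.94), HSPA8 (-0.88) and DNAJA1 (-0.63) were among these, whereas the small heat shock protein genes CRYAB (0.76) and HSPB1 (0.61) lay above 0. The heat shock median was -0.33, at percentile 0.010. Of 13 measured replication-dependent histone genes, 11 lay below 0 and the list's median was -0.42, also at percentile 0.010. H2BC12 was 2.76-fold lower on its brightest probe (-1.47) but at -0.10 on its other probe, and H3C4 (-0.79) and H2AC6 (-0.59) were within 2-fold.

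The median of the TGF-beta targets lay below the random limits, with 9 of 15 measured members below 0 and 6 above. Among these, PMEPA1 (-1.58), which inhibits TGF-beta signalling, and ID1 (-1.14), an inhibitor of DNA binding, were at least 2-fold lower. ID2 (-0.89) and SMAD7 (-0.58) lay below 0 and TGFBI (0.94) above it, and the median was -0.26 at percentile 0.73. The TGF-beta list lost its place beyond the random limits with normexp background correction (percentile 2.58) and with no filter on dim probes (percentile 44.5), where 14 of 23 members lay above 0. Among other single genes, the prostatic acid phosphatase gene ACP3 (-1.14, or -0.32 with normexp) and the prostein gene SLC45A3 (-1.11) were at least 2-fold lower, whereas KLK2 (-0.77), FKBP5 (-0.84, but 2.03 on a second probe), the prostate-specific antigen gene KLK3 (0.00) and FOLH1 (0.48) were within 2-fold.

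The levels of prostate lineage genes bear on the cell line itself, since PC3 is widely described as making no prostate-specific antigen and as having lost the alpha-catenin gene CTNNA1. KLK3 had signals of 72300 on the control and 51900 on the knockout array, SLC45A3 of 49100 and 16300, and HOXB13 of 22700 and 14800. CTNNA1 (9280 and 7750) was well above background on both arrays. Of 10 genes typically abundant in PC3, 5 were well above background, AXL at 119 and CD44 at 57.8 on the control array among them, while CAV1, MET and CXCL8 were not. The cells are therefore called by their labels only.

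**Figure D2:**
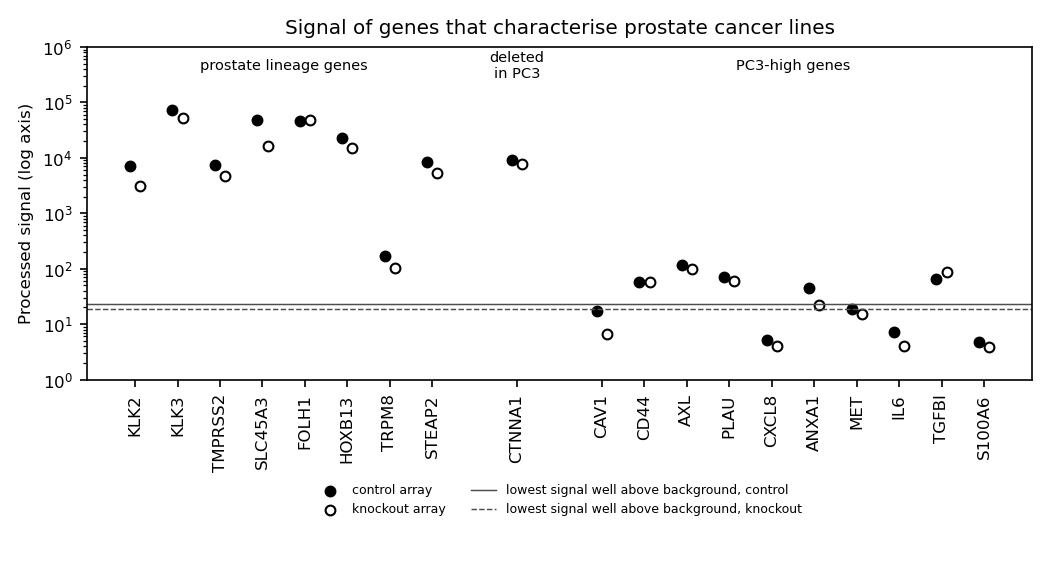
Processed signal (log axis) of genes that characterise prostate cancer lines, with the control array as filled and the knockout array as open circles; lines mark the lowest signal well above background on each array, 23.4 and 18.8. Prostate lineage genes such as KLK3 (72300 on the control array) and CTNNA1, deleted in PC3, lie above the lines, while 5 of 10 PC3-high genes do not; spots with outlier marks are kept here.

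The other lists did not stand apart. Among 12 measured mesenchymal genes, the collagen gene COL5A1 was at least 2-fold higher (1.60) and the smooth muscle actin gene ACTA2 (-1.59) and SNAI2 (-1.29) at least 2-fold lower, with a median of 0.01 (percentile 30.9). All 22 epithelial junction and keratin genes were within 2-fold, with the splicing regulator ESRP2 at -0.88, the protease gene PRSS8 at 0.79 and a median of -0.11 (percentile 6.02). All 11 measured protease and invasion genes were within 2-fold, with TIMP2 at 0.84, CTSK at -0.65 and a median of 0.24 (percentile 90.7). Of 12 stem and basal cell genes, the integrin gene ITGB4 was higher (1.12), the Notch ligand gene JAG1 lower (-1.03), and the median 0.22 (percentile 87.5). Of 15 immediate early genes, IER3 was 4.35-fold higher (2.12) and 14 were within 2-fold, with FOS at 0.89, FOSB at -0.73 and a median of 0.19 (percentile 86.6). All 14 Wnt targets were within 2-fold, with WNT7B at 0.91, NKD2 at 0.59 and a median of 0.26 (percentile 92.5). The 19 ephrin and axon guidance genes were within 2-fold, with EFNB2 at -0.86, UNC5B at 0.85 and a median of 0.09 (percentile 64.6).

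Metabolic lists also held isolated differences. Of 27 hypoxia and glycolysis genes, the enolase gene ENO2 (1.43) and the carbonic anhydrase gene CA9 (1.42) were at least 2-fold higher, and the median was 0.02 (percentile 26.4). In the NRF2 antioxidant list, the aldo-keto reductase genes AKR1C3 (1.35) and AKR1C1 (1.02), which are close paralogs, were at least 2-fold higher among 21 genes, with SLC7A11 at -0.74 and a median of 0.10 (percentile 65.1). MSMO1 (1.01) was the only 2-fold member of 22 cholesterol synthesis genes, and the median was -0.11 (percentile 5.27). The 21 fatty acid genes (FADS2 -0.61, CPT1A -0.59) had a median of 0.10 (percentile 66.4), and the 26 oxidative phosphorylation genes (SDHA 0.34, NDUFV1 0.28) a median of 0.09 (percentile 65.2). The 25 endoplasmic reticulum stress genes, with the stress factor gene ATF3 at 0.91, had a median of 0.05 (percentile 44.9), and all of these last 3 lists were within 2-fold throughout. Only 3 neuroendocrine genes were measured, among them ENO2, with a median of 0.46 (percentile 96.2). The 5 measured endothelial and fibroblast markers, PDGFRB (0.61) and COL1A1 (-0.57) among them, were within 2-fold, with a median of 0.18 (percentile 58.9).

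In total, 12 of 30 lists stood apart from their random lists, 6 higher and 6 lower, against 1.5 for genes drawn at random. Members of a list may vary together, so 1.5 is not the number expected between 2 control cultures. The lists share members: MYC is in the ribosome biogenesis, immediate early and Wnt lists, and SNAI2 in the HIC1 target and mesenchymal lists. The percentiles describe these 2 arrays only, and a difference between the arrays cannot be assigned to HIC1 rather than to the separate cultures.

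**Figure D3:**
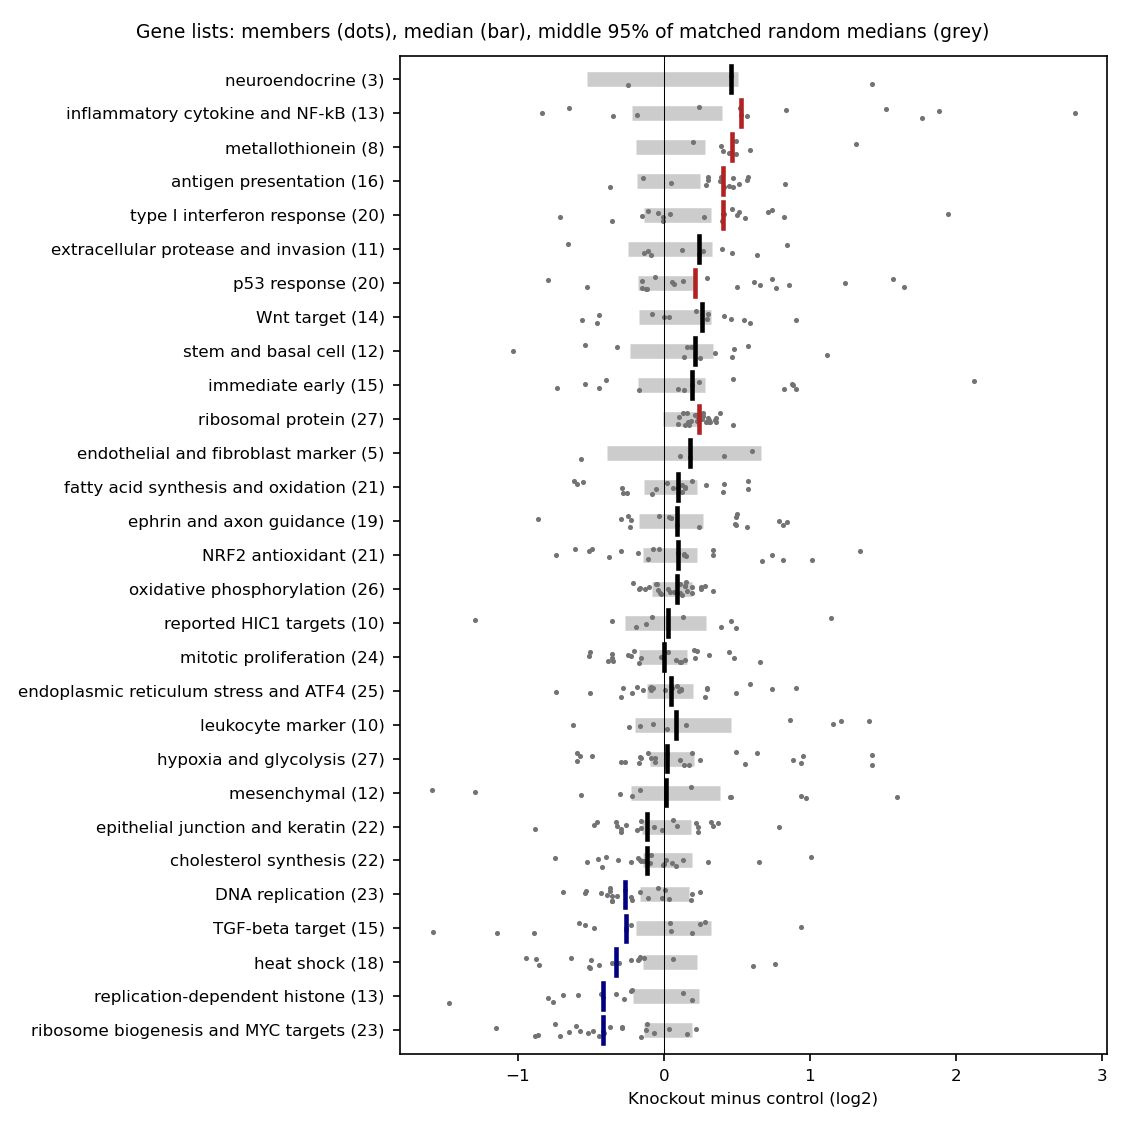
Knockout minus control differences in log2 units for 29 of the 30 gene lists, with the number of measured members in parentheses. Dots are members, bars are list medians and grey bands the middle 95% of 10000 matched random medians; 6 lists lie above their band (red bars) and 5 below it (blue bars), and the ribosomal protein list leaves that side after quantile normalization, after loess and with the stricter filter on dim probes.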

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

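The alternatives were fixed before the data were examined, except the detection mark for HIC1, which was chosen after the data were seen. List values here are medians minus the matched random median. None of the genes named by rule changed sign under any alternative that gave it a value. Of their values, 55 moved by more than the scanner error, against 604 that did not. Many of the 604 could not have done so. The percentile over all probes shifts every gene alike by less than that error, MSMO1 going from 1.01 to 0.93 with an error of 0.21. The filters on dim probes rescale no signal, and the median over probes leaves genes with a single probe unchanged. All alternatives also reuse the same arrays, so the 604 are no measure of robustness. Genes named after their values were seen, such as POLR1A and FKBP5 with second probes of opposite sign, were not covered by these counts. Of the 2-fold genes, 4 changed sign with marked spots kept and 3 with the median over probes. Of the 12 lists standing apart, all 12 stayed so with marked spots kept and with the median over probes. The percentile over all probes shifts every gene alike, so it cannot move these percentiles and is no check of them. That number was 11 after normexp, quantile normalization or loess, 10 with no filter and 9 with the stricter filter.

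With normexp, which lifts dim signals by its offset, 312 genes were at least 2-fold higher and 106 lower, and TGF-beta targets came to -0.21. Ribosomal proteins turned to -0.035 after quantile normalization and came to 0.033 after loess. With no filter on dim probes, 3034 genes were higher and 1633 lower. The lists then gave 0.025 for proteases, 0.016 for NF-kB, 0.19 for ribosomal proteins, 0.27 for metallothioneins, -0.0023 for neuroendocrine genes and -0.0022 for TGF-beta targets. The stricter filter, which leaves fewer genes, gave 145 higher and 82 lower genes. It gave 0.091 for p53, 0.16 for mesenchymal, 0.20 for interferon, 0.044 for ribosomal protein, -0.045 for Wnt, -0.73 for TGF-beta and 0.16 for ephrin genes. The median over probes gave 0.32 for HIC1 targets, which then stood apart, 0.12 for mesenchymal genes and -0.22 for the list left unnamed. With positive and significant signal as detection, genes detected in knockout only numbered 2560 and genes detected in control only 2207, and HIC1 passed on 2 arrays. Apart from the counts under the 2 filters, the cause was not tested. The alternative with the deposited value table was not run. No paired analysis was possible because each group has 1 array, and leaving out an array or splitting the samples otherwise was not possible either. Signal over background limits HIC1 and the dim 2-fold genes.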

Other observations

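The test on a gene deleted in PC3, the splitting of the second probes by list, the remark on separate cultures and the gene families below were chosen only after the results were seen. The families were formed by shared symbol prefix. Of 311 families with at least 6 measured genes, 58 lay beyond the limits of 2000 matched random lists, 39 of them lower and 19 higher in the knockout array. For genes drawn at random 15.6 would do so. Members of a family may vary together, so 15.6 is not the number expected between control cultures. Those given here are examples, picked after the results were seen. Of the families of related function, some lay beyond the limits on the same side and others within them. The lowest medians of the 39 were those of the RRP (-0.58), PSMC (-0.56), RANBP (-0.55) and ARMC (-0.53) genes. The PSMC genes, which encode proteasome ATPases, had 6 of 7 below 0, and the proteasome regulatory PSMD genes had a median of -0.30, with 12 of 14 below 0. The CCT genes of the chaperonin that folds actin and tubulin had a median of -0.34, with 7 of 8 below 0. For the MRPL genes of the large mitochondrial ribosomal subunit it was -0.21, with 40 of 49 below 0, and for the TIMM genes of mitochondrial protein import it was -0.37, with 11 of 14 below 0. Within the limits were the MRPS genes of the small mitochondrial subunit (median -0.09, percentile 7.98), the TOMM import genes (percentile 5.75), the respiratory NDUFA, NDUFB, NDUFS and COX genes (31.8 to 63.2), the HSPA and DNAJB chaperone genes (4.60 and above), and the UBE (12.4), USP (11.2) and CUL (43.3) genes of the ubiquitin system. After loess the medians were -0.55 (PSMC), -0.36 (PSMD), -0.39 (CCT), -0.23 (MRPL) and -0.36 (TIMM).

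The highest medians of the 19 higher families were those of the CCL (0.81), CAMK (0.71), IFI (0.66) and AKR (0.62) genes. All 9 AKR genes, which encode aldo-keto reductases, lay above 0. After loess the medians were 0.71 (CCL), 0.54 (CAMK), 0.58 (IFI) and 0.45 (AKR). The 48 RPL-prefixed genes had a median of 0.24, which turned to -0.03 after quantile normalization. The 376 measured pseudogenes had a median of 0.12, at percentile 99.6 of matched protein-coding lists.

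Both arrays labelled PC3 carried high KLK3 signal. RNA from PC3 cells alone is argued against by the gene deleted in that line that was examined, CTNNA1: this 1 gene was well above background on both arrays. A minor share of KLK3-positive cells in mostly PC3 RNA is argued against by the PC3-high genes, whose median percentile among detected genes of the control array was 6.33, with undetected genes counted as 0; the prostate lineage genes had 92.9. RNA from another, KLK3-positive prostate line may account for both arrays, as may files that belong to other samples, and neither was tested. The pattern is shared by both groups, so no biological explanation from the design was tested.

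Several gene lists stood apart from matched random lists. For an intensity-dependent bias as the whole cause, 11 of 12 lists stayed beyond the limits after loess, the ribosomal proteins being the exception. The random lists were already matched on level, so loess could move most percentiles little and is no independent check. For the lists pooled, errors of single probes as the whole cause are argued against by second probes, which were not used for the medians. Of these, 50 of 70 (71.43%), 16 of the 70 being ribosomal proteins, lay on their list's side of the median of all second probes. The upper limit in random draws was 61.4%. For the p53 response list 3 of 9 second probes lay on its side, but only 4 of these genes did so on the first probe and 8 of 9 kept their sign. That count says nothing for such errors and nothing against them. In the ribosome biogenesis list 4 of 6 lay on its side and 3 of 6 kept their sign, and in the list left unnamed 3 of 6 lay on its side. For these lists such errors stay open. So do they for the 4 lists with under 3 second probes (5 in all, 0 for NF-kB, 1 for metallothioneins, 2 each for interferon and TGF-beta). A difference between cultures or clones that has nothing to do with HIC1 cannot be told apart from the knockout with 1 array per group, and the loss of HIC1 stays open as the design's own explanation.

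RN7SL1 and 11 of 13 replication-dependent histone genes, which lack or mostly lack poly(A) tails, had lower values in the knockout array. A general excess of RNA without poly(A) tails in the control sample stays open: the 223 small non-coding genes lay at percentile 21.83 of matched protein-coding lists, in a test chosen after the results were seen. Other small RNAs differed in both directions beside RN7SL1 (-2.26), with RN7SK at 0.33, RMRP at 0.12, SNAR-F at -0.78 and SNORD86 at -1.30. A difference in histone messages through the cell cycle may contribute and was not tested; no explanation specific to RN7SL1 was tested.

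Copy number was examined as a hypothesis, since a difference between the control and the knockout cells could shift genes of whole chromosome stretches. Of 277 windows of 10 Mb with at least 20 measured genes, 0 had a median beyond 0.3 and beyond all matched random lists, and the largest absolute median was 0.26. Measured from the matched random median, the largest distance was -0.28, on chromosome 15 from 100000001 to 110000000, which is close to 0.3. The windows argue against shifts well beyond 0.3 over whole windows only. By their percentiles, 28 windows lay beyond the limits of 2000 random lists, against 13.9 for genes drawn at random. Of these, 1, chromosome 7 from 40000001 to 50000000 (median -0.15, or -0.21 from the random median), lay below all random lists, so smaller shifts stay open. Stretches under 10 Mb were not examined.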
